A study of Mus musculus with 5 samples.

How the data were processed

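Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 2 transcription factors and 2 histone marks in mouse hematopoietic progenitor cells. Per the labels' protocols, lineage-depleted bone marrow of C57B6 mice was transduced with retroviruses carrying HA-tagged Hoxa9 and Flag-tagged Meis1 and was grown with IL3. Hoxa9 was precipitated through its HA tag, C/EBPα with antibodies against the protein itself, and H3K4me1 and H3K27me3 with antibodies against each mark. The series held 5 libraries, 1 for each of the 4 precipitations and 1 input. A peak list was used for each precipitation, and the input library was not used here. With 1 library per group there were no replicates, so every test compared peak lists and none compared conditions or cultures.

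Per the submitters' processing notes, CASAVA 1.8.2, BWA 0.6.2 and MACS 1.4 were used with the mouse build mm9. The caller's settings, and which control library it was given, are not given in the sources used here. Per the file headers, each list gave positions, widths, summits and 4 values per peak, all made by the authors' caller and called separately in each library. The deposited tag counts were whole numbers of tags in each peak, not normalized. The deposited p score was 10 times the −log10 of the caller's p-value. The deposited fold enrichment was a linear ratio. The deposited false discovery rate was given in percent. The scores began at 50.01 or 50.02 in the 4 lists, and a score of exactly 3100 was shared by 5 Hoxa9 peaks, 231 C/EBPα peaks, 1274 H3K4me1 regions and 2558 H3K27me3 regions. Ranks at the top of a list were therefore partly ties, which were ordered by fold enrichment and then position. In shared Hoxa9 and C/EBPα-only peaks the median fold enrichment was lower above 3100 than at 3100. The scores alone cannot tell whether peaks at 3100 rank below those above it, so top ranks near that score are uncertain. The false discovery rate did not follow the score throughout: its median was 0.03% over all C/EBPα peaks and 0.38% over those with a score of 3100 or more. These values were used only to describe, rank or filter peaks within a list.

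Library totals are not given in the sources used here. The lists held 285488 tags in Hoxa9 peaks, 1408867 in C/EBPα peaks, 6242014 in H3K4me1 regions and 7470847 in H3K27me3 regions, sums that depend on how much was called and are not depths. The fewest tags in a called peak were 17, 15, 14 and 20 in the same order. Sites too weak to be called at these depths are missing from the lists, so a peak named as bound by 1 factor had no called peak of the other factor and may still have held some of it.

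A pair of peaks counted as shared if at least 1 bp was common to both. Hoxa9 peaks with a C/EBPα peak were called shared Hoxa9 peaks and the rest Hoxa9-only peaks, and C/EBPα peaks were divided in the same way. Chance levels came from 1000 circular shifts of the first list along each chromosome, inside the span that the 4 lists covered on it (2574.38 Mb in total over 20 chromosomes). The smallest p that these permutations can give is 0.001 one-sided and 0.002 two-sided. Tests were one-sided for higher overlap of the factors with each other and with H3K4me1, and two-sided wherever H3K27me3 was involved. Inside H3K4me1 regions, Hoxa9 peaks were placed at random within such regions 1000 times. Differences in median between shared and unshared peaks, and Spearman correlations across peaks, were tested with 100000 permutations, two-sided, for which the smallest p is 1e-05. The 6 tests of medians were adjusted together by the Benjamini-Hochberg method. Overlap of marks was compared between classes of peaks with Fisher's exact test, two-sided. Peaks are not replicates and neighbouring peaks are not independent, so these p-values describe the lists. Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only. Chance levels for stretches of peaks and for groups by strength or width came from 200 draws each.

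Peaks to be named were chosen by a rule: the 10 highest p scores among shared Hoxa9, Hoxa9-only and C/EBPα-only peaks, the 10 widest regions of each mark, and the 4 stretches with most shared peaks. The rule, the tests of the comparisons in the results and most alternatives were fixed before the data were examined, and the tests of explanations were added later. The gene annotation at hand was of GRCm38, another build than that of the lists, which pair no peaks with genes. Peaks are therefore named by their mm9 coordinates alone. Location relative to genes, motif content at summits and peaks near fixed gene lists had been planned and were not run.

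The overlap code was tested on simulated Hoxa9 lists of 6578 peaks set against the C/EBPα list. With 0%, 2%, 5% and 50% planted overlap, it found 1.38%, 3.18%, 6.38% and 50.7%, which includes chance overlap near 1.47%. Of 100 simulated lists without planted overlap, 3 gave a permutation p at or under 0.05 in 200 shifts each. Simulated peaks were drawn uniformly along their chromosomes, without the grouping of the real list, so this rate need not hold for grouped lists. Alternatives covered stricter thresholds, other definitions of overlap, other chance levels and leaving out chromosome X. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and matplotlib 3.10.9 were used.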

Results

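Binding of Hoxa9 and C/EBPα was mapped in mouse bone marrow progenitors transformed by Hoxa9 and its cofactor Meis1, together with H3K4me1, a mark of enhancers, and H3K27me3, the mark of Polycomb repression. Hoxa9 is a homeodomain transcription factor, and C/EBPα is a leucine zipper factor that directs myeloid differentiation. Each list came from 1 library, so no value below has a replicate error. The Hoxa9 list held 6578 peaks covering 4.57 Mb, with a median width of 651 bp and a median fold enrichment of 6.06. The C/EBPα list held 26446 peaks covering 18.0 Mb, with a median width of 639 bp and a median fold enrichment of 7.74. H3K4me1 covered 119 Mb in 100189 regions, 4.64% of the span of the lists. H3K27me3 covered 64.5 Mb in 33769 regions, or 2.51%. Numbers of peaks depend on depth, antibody and caller, and were not compared between proteins.

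The first question was how far Hoxa9 and C/EBPα occupied the same sites. Of the 6578 Hoxa9 peaks, 3742 overlapped a C/EBPα peak, a share of 56.9% (95% exact interval 55.7 to 58.1). Shifted Hoxa9 lists gave 1.47% on average and between 0.988% and 1.99%, so the observed share was 38.7 times chance. From the other side, 3764 of 26446 C/EBPα peaks overlapped a Hoxa9 peak, a share of 14.2% (13.8 to 14.7) against 0.371% by chance, or 38.4 times. The permutation p was 0.001 for both, the smallest that the shifts can give. Sharing was seen on every chromosome, with a mean of 56.7% ± 4.63 (SD over 20 chromosomes), a lowest value of 45.0% on X and a highest of 68.4% on chromosome 19. The ratio to chance depended on the settings. It was 25.7 for Hoxa9 peaks with shifts of at most 1 Mb, which gave 2.22% by chance, 17.8 with peaks extended by 500 bp and 160.0 with summits within 100 bp. The share depended on how overlap was defined and on the length of the C/EBPα list. It was 34.9% of Hoxa9 peaks and 8.67% of C/EBPα peaks if summits had to lie within 100 bp. It was 28.2% of Hoxa9 peaks with only the 6578 highest scoring C/EBPα peaks, a setting chosen after seeing the data, and 6.23% of C/EBPα peaks at a fold enrichment of 10 or more in both lists.

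The summits of both factors lay close together. The median distance from a Hoxa9 summit to the nearest C/EBPα summit was 284 bp, against 75196 bp in shifted lists. Of all Hoxa9 summits, 21.2% had a C/EBPα summit within 50 bp, 34.9% within 100 bp, 46.4% within 200 bp and 58.3% within 1000 bp. Shifted lists gave 0.110%, 0.218%, 0.434% and 2.11% for the same windows. Among shared Hoxa9 peaks the median distance was 73 bp. The 3055 pairs of summits within 200 bp had a median signed offset of 0 bp, and C/EBPα lay on the side of the higher coordinate in 49.9% of them (48.1 to 51.7). These offsets follow genome coordinates and not the strand of a binding site, so they cannot show whether the factors have a preferred order.

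**Figure D1:**
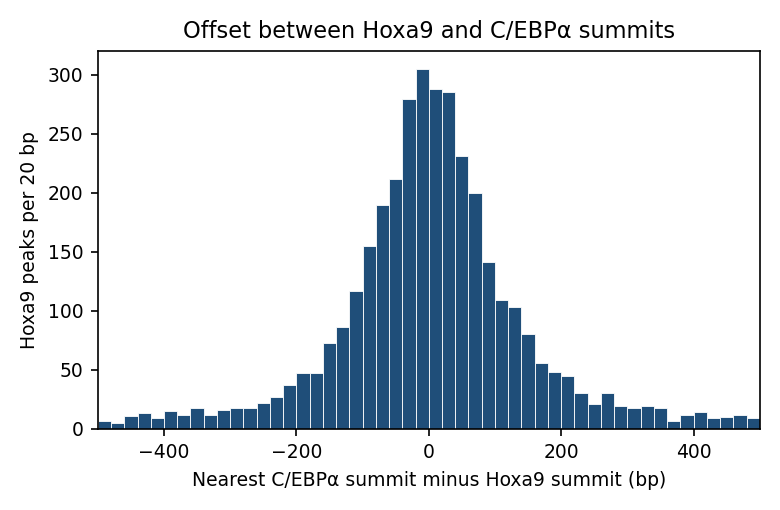
Histogram of the distance in bp from each Hoxa9 summit to the nearest C/EBPα summit (x axis, within 500 bp either side), as the number of Hoxa9 peaks per 20 bp (y axis). The distribution is centred on 0, and 46.4% of all 6578 Hoxa9 summits lie within 200 bp.

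The highest scoring shared Hoxa9 peaks were found on several chromosomes. The top score belonged to a peak on chromosome 19 from 15910831 to 15913115 (mm9), with a fold enrichment of 39.46 and a C/EBPα summit 29 bp away. Its rank above peaks with a score of 3100 is uncertain. The highest fold enrichment among the 10 was 54.65, at one of 5 peaks tied at a score of 3100, chromosome 2 from 172996505 to 172998484, where the nearest C/EBPα summit was 847 bp away. A pair of them lay on chromosome 10, from 17894647 to 17897364 (summits 80 bp apart) and from 20802609 to 20804263 (fold enrichment 49.46, summits 59 bp apart). Peaks at chromosome 13 from 109061288 to 109062717 and chromosome 9 from 124013283 to 124014734 had fold enrichments of 45.8 and 45.17. The other 4 lay at chromosome 18 from 75062234 to 75064197, chromosome 16 from 45025110 to 45026609, chromosome 8 from 82786852 to 82788312 and chromosome 9 from 63089159 to 63090633, with fold enrichments from 34.74 to 40.32. All 10 overlapped an H3K4me1 region and 0 overlapped an H3K27me3 region.

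Strong Hoxa9 binding without a C/EBPα call also occurred. The Hoxa9-only peak with the highest score, at chromosome 15 from 64089147 to 64090412, had a fold enrichment of 38.33 and lay 15431 bp from the nearest C/EBPα summit. The next was at chromosome 19 from 30377473 to 30378879, with a fold enrichment of 35.9 and a C/EBPα summit 1961 bp away. The 10 highest scoring Hoxa9-only peaks had fold enrichments from 23.51 to 38.33, and their distances to the nearest C/EBPα summit ran from 969 to 42142 bp. All 10 overlapped H3K4me1 and 0 overlapped H3K27me3. Among C/EBPα-only peaks the highest score was at chromosome 4 from 125694564 to 125695625, with a fold enrichment of 65.3 and the nearest Hoxa9 summit 49644 bp away. The 10 highest scoring had fold enrichments from 43.06 to 65.3 and scores of 3149.05 or more, so peaks at exactly 3100 were left out. Of these 10, 9 overlapped H3K4me1, the exception being chromosome 2 from 105267936 to 105269122, and 0 overlapped H3K27me3. Score did not order the top of this list by enrichment: 109 C/EBPα-only peaks tied at 3100 had a median fold enrichment of 56.57, against 48.17 in the 17 peaks above that score. The highest fold enrichment, 145.99, was among the tied peaks, at chromosome 3 from 157724541 to 157725887, a peak named after its values were seen.

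Stronger Hoxa9 peaks were more often shared. With the Hoxa9 list divided into 5 groups by p score, 36.1% of the weakest group overlapped C/EBPα, followed by 42.7%, 59.5%, 66.6% and 79.6% in the strongest. Shifted lists gave between 1.24% and 1.85% in these groups. Across peaks the score correlated with sharing (Spearman's rho = 0.326, permutation p = 1e-05, the smallest possible, over 6578 peaks that are not replicates). For C/EBPα peaks the shares were 5.88% in the weakest of 5 groups by their own score and 29.8% in the strongest. Shared Hoxa9 peaks had a median fold enrichment of 6.835 against 5.58 in Hoxa9-only peaks, a median score of 137.53 against 72.02 and a median width of 726 against 541.5 bp. Shared C/EBPα peaks had a median fold enrichment of 11.55 against 7.41, a median score of 436.73 against 166.275 and a median width of 815 against 617 bp. All 6 differences had an adjusted permutation p of 1e-05.

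**Figure D2:**
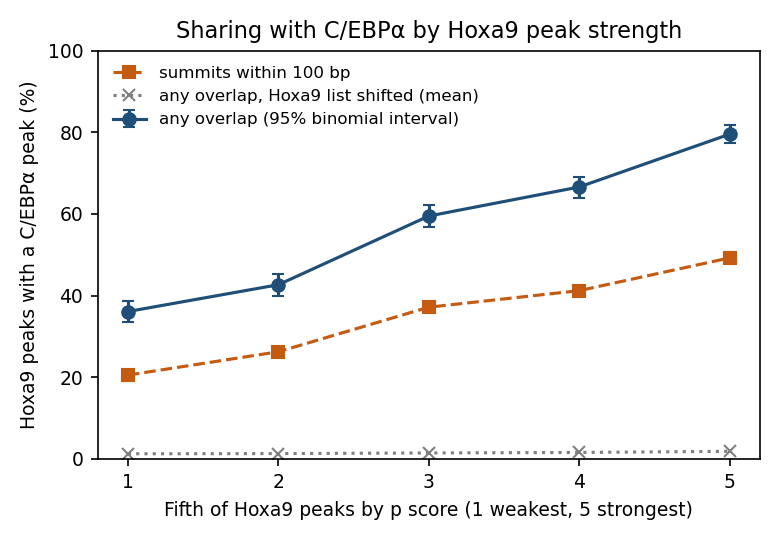
Share of Hoxa9 peaks with a C/EBPα peak (y axis, percent) in 5 groups of Hoxa9 peaks ranked by p score (x axis, 1 weakest). Circles with 95% exact binomial intervals count any overlap and rise from 36.1% to 79.6%, squares count summits within 100 bp and rise from 20.5% to 49.2%, and crosses give the mean of shifted lists, at most 1.85%.

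Both factors lay mostly in H3K4me1 regions. H3K4me1 overlapped 82.4% of Hoxa9 peaks (81.5 to 83.4) against 7.18% by chance, or 11.5 times, and 73.6% of C/EBPα peaks (73.0 to 74.1) against 7.17%, or 10.3 times (permutation p = 0.001 for both). Shared peaks were marked more often than the rest. H3K4me1 overlapped 93.5% of shared Hoxa9 peaks and 67.8% of Hoxa9-only peaks (Fisher's exact p = 3.16e-165), and 93.9% of shared and 70.2% of C/EBPα-only peaks (Fisher's exact p = 1.16e-258). The gap between classes was wide among weak Hoxa9 peaks and narrow among strong ones. In the weakest of the 5 groups, 86.7% of shared and 47.0% of Hoxa9-only peaks overlapped H3K4me1, and in the strongest 97.4% and 95.2%. This change of the gap was not tested. Over all groups the difference was 25.7 percentage points. With the Hoxa9, C/EBPα and H3K4me1 lists each cut to the upper 50% by score it was 9.13. With each cut at a fold enrichment of 10 or more it was 7.26. Sharing was counted anew among the peaks kept, so Hoxa9-only peaks then included those that overlapped only a removed C/EBPα peak. For C/EBPα the difference of 23.7 points was 12.6 at that fold enrichment. At that cut fewer peaks of every class overlapped H3K4me1, so smaller differences in points do not show a smaller contrast between the classes. With only regions and peaks at a fold enrichment of 10 or more, which left 3349 H3K4me1 regions, the overlap was 22.1% of Hoxa9 and 13.7% of C/EBPα peaks, still above chance (permutation p = 0.001 for both).

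H3K4me1 calls were thinner at shared summits than beside them. A region covered 76.6% of shared Hoxa9 summits, and 82.7% and 83.6% of the points 400 bp to either side. At Hoxa9-only summits the values were 58.1% at the summit and 57.3% and 56.8% beside it, and at C/EBPα-only summits 60.5%, 56.4% and 55.8%.

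**Figure D3:**
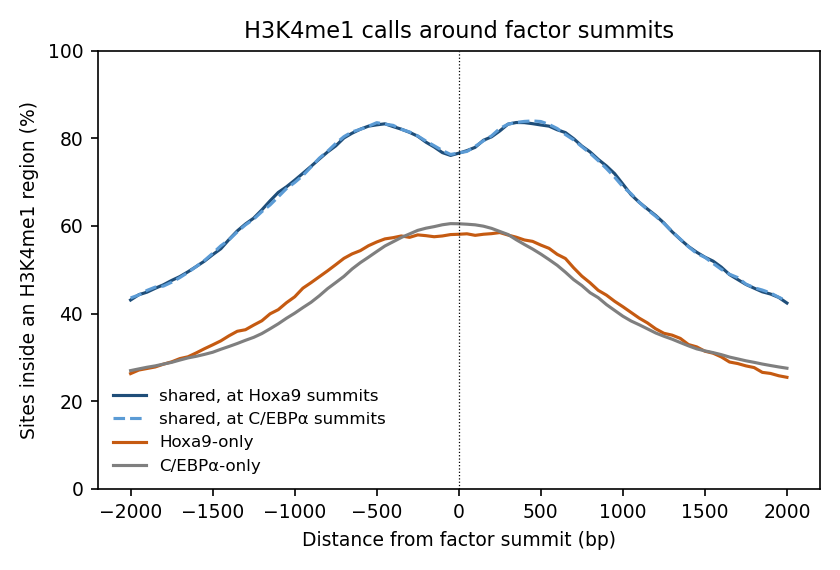
Share of sites inside an H3K4me1 region (y axis, percent) at distances up to 2000 bp from the factor summit (x axis), for shared peaks at Hoxa9 summits and at C/EBPα summits and for Hoxa9-only and C/EBPα-only peaks. Both shared curves dip at the summit, from about 83.6% to 76.6% for Hoxa9, and the curves of unshared peaks do not.

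Sharing was also set against chance inside H3K4me1 regions, a stricter level since both factors lay mostly there. Of 4515 Hoxa9 peaks with summits inside H3K4me1 regions, 2867 overlapped C/EBPα, a share of 63.5% (62.1 to 64.9). Placing the same peaks at random in H3K4me1 regions gave 18.8%, and the observed share was 3.38 times that (permutation p = 0.001). Against random places within the same H3K4me1 region, which gave 41.7%, it was 1.52 times as high (permutation p = 0.001). With sharing defined by summits within 200 bp, 51.2% were shared against 5.57% at random places in any H3K4me1 region, or 9.19 times (permutation p = 0.001).

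H3K27me3 rarely met either factor. It overlapped 98 Hoxa9 peaks, 1.49% (1.21 to 1.81) against 3.30% by chance, and 553 C/EBPα peaks, 2.09% (1.92 to 2.27) against 3.31% (two-sided permutation p = 0.002 for both, the smallest possible). Shared Hoxa9 peaks overlapped it in 1.04% of cases and Hoxa9-only peaks in 2.08% (Fisher's exact p = 0.000656), and shared C/EBPα peaks in 1.01% and C/EBPα-only peaks in 2.27% (Fisher's exact p = 7e-08). These class differences did not pass the test among peaks in the upper 50% of each list by score, nor at a fold enrichment of 10 or more. In both settings sharing was counted anew among the peaks kept. At that fold enrichment the deficit at Hoxa9 peaks, 1.27% against 1.57% by chance, did not pass either (permutation p = 0.56). At C/EBPα peaks of that fold enrichment the overlap was 0.975% against 1.57% (permutation p = 0.002). Over all 6578 Hoxa9 peaks, with the summit required to lie inside the region, it was 0.745% against 2.58% (permutation p = 0.002). The marks themselves met more often than in lists shifted along whole chromosomes. Shifts of at most 1 Mb were not run for them, so a shared preference for broad parts of a chromosome was not set apart. Of H3K4me1 regions 6.85% overlapped an H3K27me3 region against 3.74% in shifted lists, or 1.83 times (two-sided permutation p = 0.002), and of H3K27me3 regions 14.6% overlapped H3K4me1 against 8.95%.

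The widest H3K27me3 region, at chromosome 8 from 126061025 to 126151860, spanned 90.836 kb. Its 0.680 tags per bp stood apart from the 0.190 to 0.267 tags per bp of the other 9 of the 10 widest. The following regions lay at chromosome 6 from 52152460 to 52232845 (80.386 kb), chromosome 11 from 96109310 to 96186459 (77.15 kb) and chromosome 2 from 74480198 to 74555361 (75.164 kb). A second region on chromosome 11, from 96024851 to 96071438, spanned 46.588 kb. The 10 widest held 1 Hoxa9 and 2 C/EBPα summits in total, and all 10 touched an H3K4me1 region. The widest H3K4me1 region, at chromosome 8 from 126774978 to 126800644, spanned 25.667 kb and held 2 Hoxa9 summits and 1 C/EBPα summit. All of the 10 widest held C/EBPα summits, 20 in total, 3 held Hoxa9 summits, and 0 overlapped H3K27me3. For neither mark was a chance level computed for these counts, and wide regions meet more peaks by chance.

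Some shared peaks grouped along chromosomes. With gaps of up to a fixed limit, midway between 0 and 25 kb, 61 stretches held 3 or more shared Hoxa9 peaks and 313 held 2. Most shared peaks, 2920 of 3742, stood alone, and 22.0% lay in stretches of 2 or more. Drawing as many peaks at random from the Hoxa9 list gave 39.6 stretches of 3 or more on average and 53 at most in 200 draws. Shifted lists gave at most 2, but only about 1.47% of their Hoxa9 peaks were shared. With so few shared peaks they cannot show whether shared peaks group. The stretch with most shared peaks, 6, lay at chromosome 2 from 84854680 to 84876950 and held 8 C/EBPα summits, and the random draws reached stretches of up to 9. Stretches of 5 lay at chromosome 16 from 45018678 to 45039371, chromosome 19 from 20463593 to 20485038 and chromosome 6 from 119327492 to 119349803. None of these 4 held an H3K27me3 summit. The number of stretches of 3 or more depended on the gap, with 20 at 5 kb and 125 at 25 kb, and was 31 with sharing defined by summits within 200 bp. No chance level was computed for these alternatives.

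Chromosome X differed from the autosomes in all 4 lists. It carried 0.805 Hoxa9 peaks per Mb against an autosomal median of 2.65, 3.50 C/EBPα peaks against 10.5 and 7.28 H3K4me1 regions against 40.5. H3K27me3 calls were more numerous there, with 25.8 regions per Mb on X against a median of 12.6 over 19 autosomes and a highest autosomal value of 22.7 on chromosome 11. The excess was in the number of calls and not in covered length: H3K27me3 covered 2.55% of X, the same as the autosomal median of 2.55%, and 4.68% of chromosome 11. At a fold enrichment of 10 or more, X had 0.836 regions per Mb against an autosomal median of 1.86. No test was made of these densities.

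**Figure D4:**
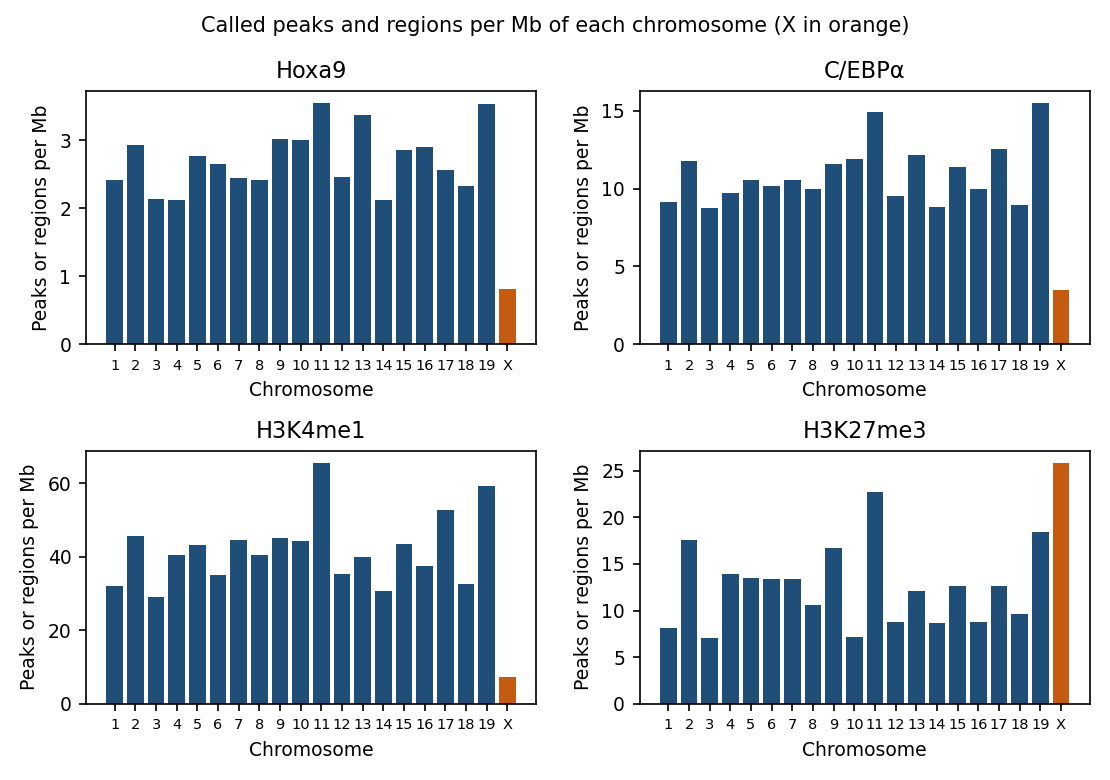
Called peaks or regions per Mb (y axes, each from 0) on chromosomes 1 to 19 and X (x axes) for Hoxa9, C/EBPα, H3K4me1 and H3K27me3, 1 library each, with X in orange. X is lowest for the first 3 lists and highest for the number of H3K27me3 regions, at 25.8 per Mb, although its covered share of 2.55% is close to the autosomal median.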

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

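Of 127 alternatives to 21 results, 119 kept the direction and the side of the threshold or stayed near the value, 5 kept the direction and no longer passed the test, 3 moved a count of stretches by over 1.5 times and 0 reversed. Among the 119, 14 moved the value itself by over 1.5 times. The 119 also include settings that removed no peak, named in the next paragraph, whose outcome was fixed in advance. All 5 that no longer passed concerned H3K27me3. At a fold enrichment of 10 or more, 1.27% of Hoxa9 peaks overlapped it (permutation p = 0.56), with 1099 Hoxa9 peaks left of 6578. The difference between shared and Hoxa9-only peaks was -0.47 percentage points in the upper 50% of each list by score (Fisher's exact p = 0.269) and -0.891 at a fold enrichment of 10 or more (p = 0.281). Between shared and C/EBPα-only peaks it was -0.478 (Fisher's exact p = 0.146) and -0.315 (p = 0.662). These settings keep fewer peaks and regions, and the class differences in them count sharing anew among the peaks kept. Why they no longer passed was not tested further. The 61 stretches of 3 or more shared peaks became 20 with a gap of 5 kb, 125 with a gap of 25 kb and 31 with summits within 200 bp, as a shorter gap or a stricter definition leaves fewer.

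The alternatives without chromosome X, without peaks of 0.5 or more tags per bp, and with a shortened C/EBPα list were chosen after seeing the data. Of the 14 that moved the value by over 1.5 times, 2 concerned the share of Hoxa9 peaks with C/EBPα (34.9% and 28.2%) and 2 the share of C/EBPα peaks with Hoxa9 (8.67% and 6.23%). H3K4me1 overlap fell to 22.1% of Hoxa9 and 13.7% of C/EBPα peaks at a fold enrichment of 10 or more, and 3 class differences in it to 9.13, 7.26 and 12.6 points. H3K27me3 overlap became 0.745% of Hoxa9 peaks and 0.975% of C/EBPα peaks. At a fold enrichment of 10 or more, the differences of medians became 115.8 (Hoxa9 score), 74 bp (Hoxa9 width) and 448.3 (C/EBPα score). The shortened list gave the lowest share of Hoxa9 peaks with C/EBPα, 28.2%, against 61.2% with peaks extended by 500 bp, the highest. Limiting the false discovery rate to 1% removed no Hoxa9, C/EBPα or H3K4me1 peaks, and restricting the lists to autosomes and X removed none at all, so these settings test nothing there. Location relative to genes, gene lists and motifs, with their other settings, were not run, since no mm9 annotation or sequence was used here. With 1 library per precipitation, no alternative could leave out a replicate, and weak sites below the calling threshold stay unseen.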

Other observations

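The tests of the H3K4me1 gap at shared summits and of false weak calls were chosen only after the result was seen, and a first control for the gap, points drawn anywhere in H3K4me1 stretches, was replaced by the one given here.

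H3K4me1 regions differed by width in how often they held the factors. In the narrowest of 5 groups, with a median width of 439 bp, 1.60% overlapped a Hoxa9 peak, 6.96% a C/EBPα peak and 0.813% both. In the widest group, with a median width of 2415 bp, the shares were 17.8%, 46.9% and 13.6%. Wider regions meet more peaks by chance, but the ratio to shifted lists also rose, from 5.32 to 18.3 times for Hoxa9 and from 5.73 to 12.6 times for C/EBPα. Over all regions, 6.22% overlapped Hoxa9 and 19.9% overlapped C/EBPα.

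Hoxa9, Hoxb9 and Hoxd9 lie on chromosomes 6, 11 and 2 in the GRCm38 annotation, and the second to the fifth of the widest H3K27me3 regions lay on these chromosomes. Hoxc9 lies on chromosome 15, which held 0 of the 10 widest. Whether the regions on chromosomes 6, 11 and 2 lie in the Hox clusters was not tested. A set of 14 windows held peaks with 0.5 or more tags per bp and a fold enrichment under 5. Of these windows, 5 were called in 3 lists and 0 in all 4, and all 5 of their Hoxa9 peaks were shared with C/EBPα.

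H3K27me3 calls per Mb were most numerous on chromosome X, at 2.05 times the autosomal median, although they covered 2.55% of it, the same as the autosomal median of 2.55%. The excess lay among regions with a fold enrichment under 10, since the ratio was 0.450 at 10 or more. The ratio also fell at that cut in the lists without an excess on X. It fell from 0.304 to 0.192 for Hoxa9, from 0.332 to 0.261 for C/EBPα and from 0.180 to 0.00449 for H3K4me1. The fall is therefore not particular to H3K27me3 and does not show what the excess is. Regions on X were also narrower, with a median width of 707 against 953 bp, and had a median fold enrichment of 5.42 against 6.09. Copy number and mappability of X were not tested, the labels do not give the sex of the mice, and no biological explanation was tested.

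The gap in H3K4me1 calls at shared summits was set against gaps placed without regard to the factors. Among 3332 shared Hoxa9 summits in H3K4me1 stretches joined over gaps of up to 1 kb, coverage 400 bp to either side exceeded coverage at the summit by 4.49 percentage points. Points at the same relative place in other stretches of like width gave -2.66 on average and -0.735 at most in 1000 draws, which argues against randomly placed gaps. Hoxa9-only summits gave -6.68, inside the range of their own draws, -10.3 to -5.40. Effects of the input or of the strength of shared peaks stay open, as neither was tested, and no biological explanation was tested.

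Sharing with C/EBPα rose with Hoxa9 peak strength by 43.5 percentage points from the weakest to the strongest of 5 groups. Wider peaks touching more often does not account for all of it. With summits within 100 bp sharing still rose by 28.7 points, from 20.5% to 49.2%. That stricter definition lowered sharing in every group, so the smaller rise does not show how much width adds. Location in H3K4me1 does not account for all of it either, as the rise among Hoxa9 peaks that overlap H3K4me1 was 28.9 points. Among those outside H3K4me1 it was 55.1 points, from 12.4% of 509 peaks to 67.5% of 40. False calls among weak Hoxa9 peaks stay open. The weakest group was shared at 36.1%, which is 29.2 times the level of shifted lists. That level cannot exclude false calls that recur at the same places in both libraries. How many false calls the group holds cannot be told apart from weaker co-occupancy with 1 library.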
